A study of Mus musculus and synthetic construct with 33 samples.

How the data were processed

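The series measured polyA RNA by sequencing in organs of mouse embryos at embryonic day 14.5 and, separately, a massively parallel reporter assay of the linc-p21 locus. The mouse libraries came from wild-type (WT) and homozygous mutant (KO) embryos of the Trp53cor1tm1.1Vlcg strain, on a mixed 129S6/C57BL/6 background per the labels. The groups were heart (3 WT, 3 KO), hindlimb (3 WT, 3 KO), liver (5 WT, 4 KO) and lung (3 WT, 3 KO), 27 libraries from 7 litters. The reporter assay had 3 libraries of tag RNA from C2C12 cells, a mouse myoblast line, and 3 libraries of the vector DNA pool. Organs were homogenized in TRIzol and libraries made with the TruSeq RNA kit v2, per the labels' protocols. Reporter libraries were made from cDNA with indexed primers against the tag-carrying GFP, per the labels' protocols.

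The submitters' processing notes name CASAVA 1.8.2, TopHat2 and the mouse build mm10. Per the file headers, the authors gave 1 FPKM value (fragments scaled by transcript length and library size) per gene and genotype, pooled over the libraries of that genotype. The log2 fold change of KO over WT, the test statistic (a score with no fixed range), the p-value and the q-value of each gene were also deposited by the authors, per the file headers. The program that made them is not given in the sources used here. Of the 26754 genes listed, the authors tested 15336 in heart, 16526 in hindlimb, 14275 in liver and 14709 in lung, per the status column of the deposited tables. The smallest deposited p-value was 5e-05 in every organ, shared by 30 genes in heart, 67 in hindlimb, 51 in liver and 87 in lung. Genes at that value have the same q-value within an organ, so their q-values neither rank them nor compare organs. Adjusting the deposited p-values over the tested genes by the Benjamini-Hochberg method returned the deposited q-values to within 1e-06.

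The reporter values are deposited as the fraction of all tag reads in each library, called the share below, per the file headers and the values. The deposited ratio of each tag is the authors' median RNA share over their median vector share, and it was not used here. In every library all shares above 0 were whole multiples of 1 step, within a tolerance of 0.001, and the lowest was 40 steps, so tags below that level are listed at 0. The listed tags made up 20.3%, 20.6% and 20.1% of the 3 RNA libraries and 17.8% of each vector library. Read depth is not stated for either assay. If 1 step is 1 read, reporter counts and depth could be worked out from the shares. That was not done, so no counting intervals are given.

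Values per library were not used here for the organs, because the tables hold 1 value per genotype. The tests planned before the data were examined needed counts or values per library, and for the organs they were replaced by the authors' own test with a q-value under 0.05 taken as a call. A model of organ by genotype, gene set tests with an inter-gene correlation, litter as a block, sex as a covariate and leaving out single libraries were therefore not run for the organs. Organ values carry no standard deviation. Fold changes are not given where either genotype is listed at 0. Calls on chromosome 17 were compared with calls on all other chromosomes by Fisher's exact test, two-sided. Neighbours were genes whose start lay within 1 Mb of the start of Trp53cor1. Shared calls were counted per pair of organs and direction and set against the product of both numbers of calls over the genes tested in both.

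The 21 gene lists, fixed before the data were examined, covered locus neighbours, p53 targets, proliferation, other CDK inhibitors and the RB family, hypoxia and glycolysis, immediate early genes, interferon response, erythroid cells, myeloid cells and megakaryocytes, endothelium, hepatoblasts, cardiomyocytes, skeletal muscle, cartilage and bone, limb patterning, epidermis, lung epithelium, mesenchyme and smooth muscle, neurons and Schwann cells, Y-linked genes and X inactivation. Each list was counted at the q-value over all genes and again adjusted over the list alone. For lists with at least 5 tested members, the median log2 fold change was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. That percentile describes these tables and is not a test over animals. Tested on simulated data, 2.5% of 40 unshifted lists of random heart genes lay above the 97.5 percentile, and 100% did with a shift of 0.3 on the log2 scale. Genes of a real list can vary together, which random genes do not copy. The lower edge and the other organs were not checked.

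For the reporter assay, the planned test on tag counts was replaced by limma 3.58.1 (R 4.3.3) on log2(share + 1e-05), with the shares of the 5 tags of a tile summed, a mean-variance trend in the moderated test, 3 RNA against 3 vector libraries, two-sided, and Benjamini-Hochberg adjustment over tiles at 0.05. Tiles above 0 in all 3 vector libraries were tested, 431 of 445. Folds are on the log2(share + pseudocount) scale, which understates the change of low tiles. Tested on simulated data of 431 tiles, the script recovered 100% of 200 tiles changed 1.5-fold with 8 false calls, and 100% of 200 tiles changed 2-fold with 9 false calls. The simulation gave all tiles of a group the same spread, as many rises as falls, and no tags lost at the low end. Its recovery does not carry over to low tiles or to a general shift. The labels do not say whether the 3 RNA libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Tile positions are 1-based mm10 coordinates as the file gives them, and exons of Trp53cor1 come from the organ tables.

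Named genes followed a rule fixed before the data were examined: Trp53cor1 and Cdkn1a in each organ, every neighbour past the threshold, the 8 largest rises and 8 largest falls among calls, and up to 4 members with the smallest p of each list. Its condition of no overlap between libraries could not be applied. In the reporter assay the rule took the 10 tiles with the largest RNA excess, the 5 with the largest deficit, and runs of at least 2 neighbouring tiles called in 1 direction. Other genes named below were chosen after their values were seen: LacZ, Glo1, Dnah8, Rnps1, Rps2, and the cardiac genes Sln, Nppa, Myl2, Myl3 and Myh7 in lung. Some genes that met the rule, and a test of retrocopy reads that needed one of them, are not reported here. Alternatives covered pseudocounts, filters on low values, the window, chromosome 17, scaling, tags and single libraries, with their effect given at the end. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for all other steps.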

Results

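RNA was profiled in heart, hindlimb, liver and lung of mouse embryos at E14.5 that carried or lacked linc-p21 (Trp53cor1), a long noncoding RNA gene next to Cdkn1a. In all, 27 organ libraries were compared by genotype within each organ. A massively parallel reporter assay, in which short pieces of the locus are linked to tags in a reporter RNA, covered the locus with 445 tiles of 90 bases, spaced 49 bases apart, and 5 tags per tile. It had 3 libraries of tag RNA from C2C12 mouse myoblasts and 3 of the vector DNA. The tables of the organs hold 1 value per genotype, so no spread between embryos accompanies them, and read depth is not stated for either assay.

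The first comparison asked what the mutation did to the targeted gene and to Cdkn1a, which encodes the cell cycle inhibitor p21. Trp53cor1 (ENSMUSG00000085912.1; mm10 chromosome 17, 29057474 to 29078961, minus strand) was 0.852 FPKM in WT heart and listed at 0 in KO heart in the authors' deposited table (q = 0.0256). It was 0.710 FPKM in WT hindlimb and listed at 0 in KO hindlimb in the authors' deposited table (q = 0.0123). Liver (0.0351 FPKM in WT, listed at 0 in KO) and lung (0.104 and 0.00505 FPKM) were too low to be tested in the authors' deposited table. LacZ, the bacterial reporter gene of the targeted allele, was listed at 0 in WT hindlimb and at 3.09 FPKM in KO hindlimb in the authors' deposited table (q = 0.0123), and it was not tested in the other 3 organs.

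Cdkn1a (ENSMUSG00000023067.7; chromosome 17, 29090979 to 29100722, plus strand), whose start lies 12018 bases from the start of Trp53cor1, was lower in all 4 KO organs. In heart it went from 20.5 to 6.84 FPKM, a log2 fold change of -1.59 (q = 0.0256), in the authors' deposited table. The largest change in Cdkn1a was in hindlimb, from 35.7 to 7.92 FPKM, a log2 fold change of -2.17 (q = 0.0123), in the authors' deposited table. Liver went from 3.92 to 1.39 FPKM (log2 fold change -1.49, q = 0.0140) and lung from 3.14 to 1.40 FPKM (-1.17, q = 0.00845) in the authors' deposited table. Whether the change in Cdkn1a differed between organs was not tested.

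**Figure D1:**
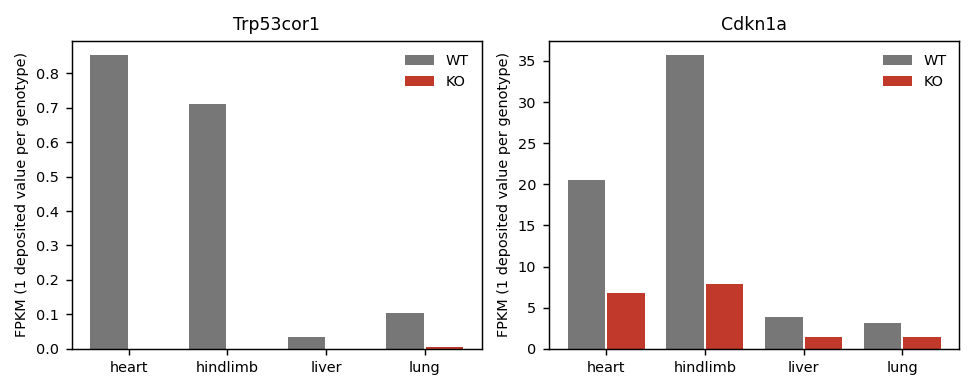
FPKM of Trp53cor1 (left) and Cdkn1a (right) in WT (grey) and KO (red) organs, 1 deposited value per genotype and so no error bars. Cdkn1a was lower in KO in each of the 4 organs, for example 35.7 against 7.92 in hindlimb.

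Other genes of the locus were examined next. Of 54 annotated genes within 1 Mb of Trp53cor1, the authors' deposited table tested 32 in heart, 37 in hindlimb, 32 in liver and 30 in lung. Cdkn1a alone was called in heart, hindlimb and lung, and liver added Clps, which encodes pancreatic colipase and rose from 1.72 to 6.96 FPKM (log2 fold change 2.02, q = 0.0140) in the authors' deposited table. Other genes of pancreatic enzymes, Ctrb1 and Cpa1 on other chromosomes, rose in the same KO livers. Adjusted over the list alone, the counts were 1, 1, 2 and 2, and the gene added in lung was Cpne5, a copine, at a log2 fold change of -1.26 (q = 0.149) in the authors' deposited table. The list of locus neighbours fixed in advance reached further and had 3 called members in each organ, and 3, 4, 6 and 4 adjusted over the list alone. Beyond 1 Mb, Glo1, the glyoxalase that clears methylglyoxal, rose in all 4 organs, from 79.9 to 189 FPKM in heart and from 180 to 344 FPKM in liver in the authors' deposited table.

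Calls were concentrated on chromosome 17, which carries the locus. It held 10 of 35 calls in heart, 19 of 103 in hindlimb, 21 of 58 in liver and 14 of 104 in lung. The odds ratios against all other chromosomes were 7.86 (Fisher's exact test, p = 4.49e-06), 4.45 (p = 5.61e-07), 10.7 (p = 3.57e-13) and 3.02 (p = 0.000610). Adjusted over the 4 organs, these p-values were 5.99e-06, 1.12e-06, 1.43e-12 and 0.000610. The test treats genes as independent units, but linked genes of the same embryos can change together. Its p-values therefore do not measure the spread between embryos. The called genes included Rnps1, a factor of the exon junction complex, which fell in all 4 organs, from 45.2 to 27.2 FPKM in heart in the authors' deposited table. Ift140, a ciliary transport gene, went from 91.8 to 6.01 FPKM in liver (log2 fold change -3.93, q = 0.0140) in the authors' deposited table.

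**Figure D2:**
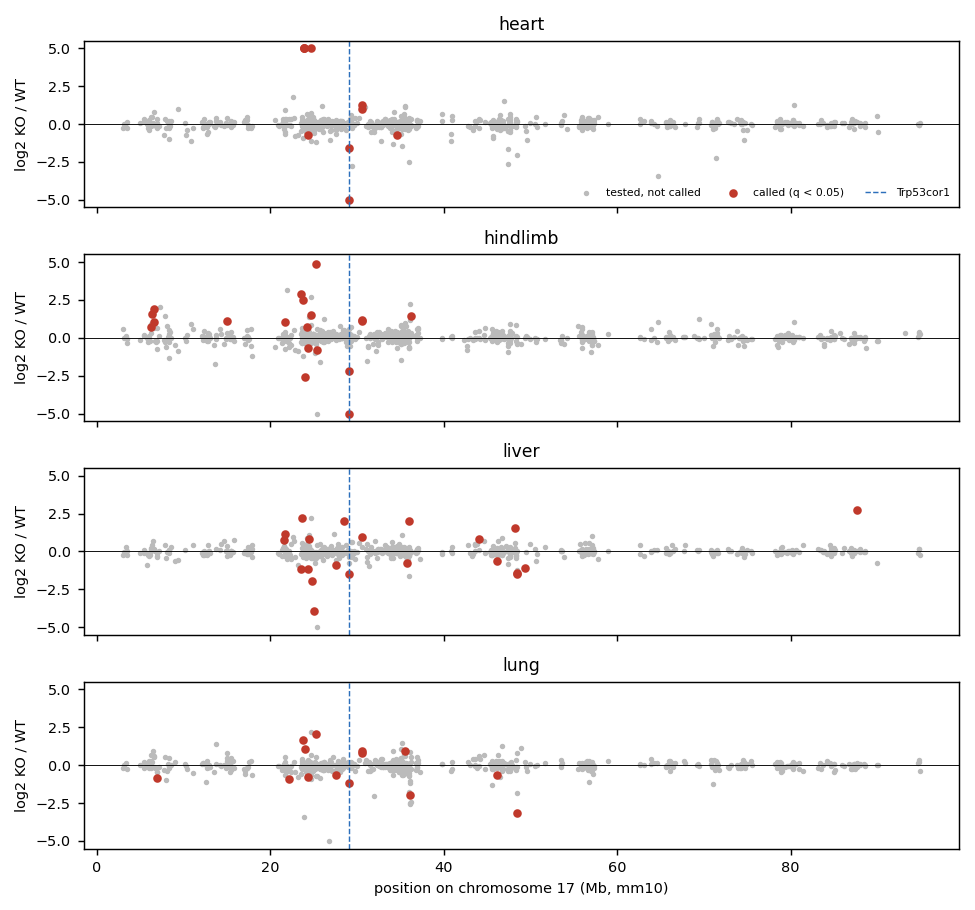
Log2 fold change of KO over WT (vertical) against gene start on chromosome 17 (horizontal, Mb) for every tested gene in each organ; red points passed q under 0.05, grey did not, and changes beyond the axis, including genes listed at 0 in 1 genotype, are drawn at its edge. Chromosome 17 held 21 of the 58 calls in liver.

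In heart, 35 genes were called, 11 higher and 24 lower in KO. Adjusted without chromosome 17, 4 were higher and 17 lower. The fall was largest, among genes above 0 in both genotypes, for Uts2b, a urotensin peptide (2.05 to 0.294 FPKM, log2 fold change -2.80), and Afp, the fetal liver protein alpha-fetoprotein (10.3 to 1.71 FPKM, -2.58), in the authors' deposited table. Serpina6, which encodes corticosteroid-binding globulin (-2.42), Fgf12 (-2.08), Alb, serum albumin (-1.87), Vsnl1 (-1.87) and Hemgn, a blood precursor gene (-1.74), also fell on the log2 scale in the authors' deposited table. Gm9825 (3.54), Rps2-ps10 (2.89) and Spp1, the matrix protein osteopontin (1.56), rose on the log2 scale in the authors' deposited table. Dcpp1, Dcpp2, Dcpp3 and Npw, all on chromosome 17, were listed at 0 in WT and at 2.47, 1.26, 0.337 and 0.426 FPKM in KO in the authors' deposited table.

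Among the lists of cell types, red cell and hepatoblast genes had lower calls in heart. Of 24 tested erythroid genes, 2 fell (8 adjusted over the list alone): Slc4a1, the anion exchanger of red cells (log2 fold change -1.03), and Hbb-bh1, an embryonic globin (-0.83), in the authors' deposited table. Afp and Alb were the 2 of 12 hepatoblast genes called (4 adjusted over the list alone), and the list's median of -1.03 lay at percentile 0 of random lists. Spp1 was the 1 called gene of 14 in cartilage and bone (1 adjusted over the list alone). Of 24 cardiomyocyte genes none was called in heart, with 4 at an unadjusted p under 0.05. The medians of the cardiomyocyte list (-0.09) and the erythroid list (-0.34) also lay at percentile 0.

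In hindlimb, 103 genes were called, 45 higher and 58 lower in KO, and muscle and skin genes were among those that fell. All 22 skeletal muscle genes had lower values in KO and 5 were called (8 adjusted over the list alone), including Ckm, muscle creatine kinase (6.90 to 2.75 FPKM, log2 fold change -1.33), and Mylpf, a fast myosin light chain (642 to 439 FPKM, -0.55), in the authors' deposited table. All 12 epidermal genes were lower and 4 were called (9 adjusted over the list alone), among them the keratin genes Krt77 (-0.90) and Krt10 (-0.66) in the authors' deposited table. Of 17 cardiomyocyte genes, several of which skeletal muscle also uses, 3 were called lower (10 adjusted over the list alone, with 1 higher), including Myh7 at -0.66 and Tnnt2 at -0.53 in the authors' deposited table. Of 21 cartilage and bone genes, the bone matrix genes Spp1 (35.3 to 7.96 FPKM, log2 fold change -2.15) and Ibsp (158 to 74.7 FPKM, -1.08) fell, while Sox9, the regulator of early cartilage, rose (12.7 to 19.2 FPKM, 0.59), in the authors' deposited table. Adjusted over the list alone, 5 rose and 3 fell, and 15 of the 21 were higher, with a median of 0.15.

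Some globin genes rose in the same limbs. Of 22 erythroid genes 5 rose (5 adjusted over the list alone), all globins, among them embryonic Hbb-y (385 to 782 FPKM, log2 fold change 1.02) and Hbb-bh1 (3.34 to 9.65 FPKM, 1.53), in the authors' deposited table. The adult globins Hba-a1 (190 to 314 FPKM, log2 fold change 0.72) and Hba-a2 (164 to 255 FPKM, 0.64) were also called higher in the authors' deposited table. The adult globins Hbb-bs and Hbb-bt were not called. Of 22 limb patterning genes none was called over all genes, 10 had an unadjusted p under 0.05, and 7 were higher adjusted over the list alone, with a list median of 0.37 at percentile 100. The neutrophil genes S100a8 (-1.47) and S100a9 (-1.73) were the 2 called of 14 myeloid genes (2 adjusted over the list alone), and Ltf (-2.51) and Ngp (-2.28), also neutrophil granule genes, fell in the authors' deposited table. Further large changes were in Tpsab1, a mast cell tryptase (4.84), Zscan10 (2.92), Prss41 (2.52), the opioid receptor Oprk1 (2.09), Prss27 (-2.56) and Dmp1, a bone matrix gene (-1.77), in the authors' deposited table. Tpsab1, Zscan10, Prss41 and Prss27 lie on chromosome 17. The next tested gene after Tpsab1, the tryptase gene Tpsb2, was called lower (-0.82) in the authors' deposited table. WT hindlimbs came from 2 litters and KO hindlimbs from 2 litters, with 1 litter shared by label.

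In liver, 58 genes were called, 43 higher and 15 lower in KO. Adjusted without chromosome 17, 29 were higher and 4 lower. Among the largest rises were Ctrb1, a pancreatic chymotrypsinogen (1.39 to 24.7 FPKM, log2 fold change 4.15) and Cpa1, a pancreatic carboxypeptidase (1.26 to 9.59 FPKM, 2.93), in the authors' deposited table. Cnn1, a smooth muscle calponin (2.94), Fxyd3 (2.90), Krt15 (3.09) and Myh6, an atrial myosin (2.90), also rose on the log2 scale in the authors' deposited table. Slc15a2 (-2.13), Meiob (-1.93), Gm4737 (-1.57), Tspo2 (-1.49) and Unc5cl (-1.40) fell, and Ifi202b went from 0.756 FPKM to a listed 0, in the authors' deposited table. At least Tspo2 among these lies on chromosome 17.

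Mesenchymal and epithelial lists were among those with called members in liver. Acta2 (0.66), Myh11 (1.91) and Col1a2 (0.50) were the 3 called of 16 mesenchyme and smooth muscle genes (6 adjusted over the list alone) in the authors' deposited table. Epcam (2.74) and Cldn6 (2.21) were called of 11 lung epithelium genes, both genes of many epithelia and both on chromosome 17, in the authors' deposited table (2 adjusted over the list alone). Krt5 (2.05) and Krt15 were called of 5 epidermal genes (3 adjusted over the list alone), Stmn2 (2.21) of 5 neuronal genes (1), Spp1 (1.63) of 14 cartilage and bone genes (3) and Myh6 of 15 cardiomyocyte genes (3), all higher, in the authors' deposited table. Ier3 (-0.73), on chromosome 17, was the 1 called of 15 immediate early genes (1 adjusted over the list alone) in the authors' deposited table. None of 20 hepatoblast genes or 24 erythroid genes was called in liver, with 2 in each list at an unadjusted p under 0.05. The hepatoblast median of 0.12 lay at percentile 100 of random lists, and the erythroid median of -0.04 at percentile 30.02.

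In lung, 104 genes were called, 13 higher and 91 lower in KO, and heart muscle genes were the fixed list with the most calls. Of 23 cardiomyocyte genes 12 fell (15 adjusted over the list alone), with a list median of -3.45 at percentile 0. Myl7, the atrial myosin light chain, went from 342 to 13.6 FPKM (log2 fold change -4.66), and Myl4 from 179 to 7.55 FPKM (-4.57), in the authors' deposited table. Tnnt2, cardiac troponin T (108 to 4.58 FPKM, -4.56), Mybpc3 (-4.69), Csrp3 (-4.69) and Ankrd1 (-6.02) fell alike in the authors' deposited table. Bmp10, a growth factor of the developing heart, Cox8b and Hspb3 were listed at 0 in KO lung and at 0.981, 3.44 and 0.945 FPKM in WT lung in the authors' deposited table. Myl2, the ventricular light chain, fell too but from a low level, 1.38 to 0.120 FPKM (log2 fold change -3.52, q = 0.00845), in the authors' deposited table. WT heart had 10103 FPKM of Myl2 in the authors' deposited table of that organ, which was scaled separately.

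Other lists had fewer called members in lung. Ckm (-2.94) and Myh3 (-1.64) fell among 9 skeletal muscle genes (3 adjusted over the list alone), Afp (-1.49) and Alb (-1.31) among 11 hepatoblast genes (3), and Krt5 (-2.22) among 8 epidermal genes (5), in the authors' deposited table. Gm9825 (2.45), Tpsab1 (2.04), Prss41 (1.64), Rps2-ps10 (1.57) and Prss22 (1.06) rose, the Y-linked Gm21857 was also higher, and Srp54a was listed at 0 in WT and 0.581 FPKM in KO, in the authors' deposited table. Tpsab1, Prss41 and Prss22 lie on chromosome 17. Of 17 lung epithelium genes none was called, with 1 at an unadjusted p under 0.05. The median of that list, 0.08, lay at percentile 99.17 of random lists.

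**Figure D3:**
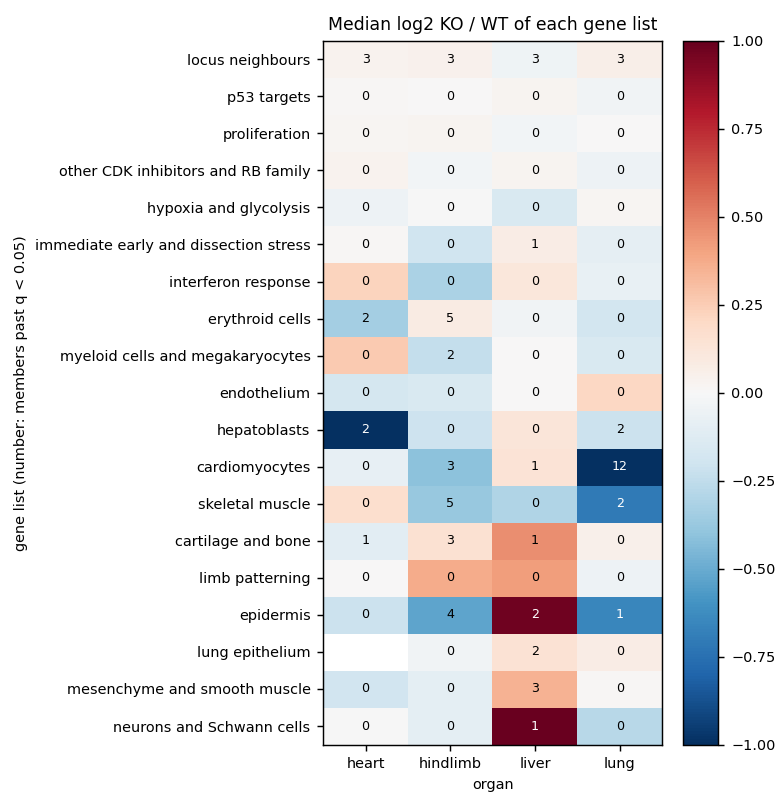
Median log2 fold change of KO over WT (colour, which ends at -1 and 1) of each gene list with at least 5 tested members (vertical) in each organ (horizontal), with the number of members past q under 0.05 printed in each field. Cardiomyocyte genes in lung stood out, with 12 called and a median of -3.45.

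Lists tied to p53 or to the known function of p21 had no called member in any organ. Of the p53 targets, 32 were tested in heart and 31 in each other organ; 0 were called by the authors' test, 5 values over the 4 organs had an unadjusted p under 0.05, and the medians lay between -0.03 and 0.03. Of 28 proliferation genes, 0 were called and 0 had an unadjusted p under 0.05, with medians between -0.02 and 0.03. The other CDK inhibitors and the RB family had 0 calls, 1 unadjusted p under 0.05, and medians between -0.05 and 0.03. Genes of hypoxia and glycolysis, interferon response and endothelium, Y-linked genes and X inactivation also had 0 calls in the 4 organs. Unadjusted p-values under 0.05 in these lists numbered 1, 3, 1 and 1 for hypoxia in heart, hindlimb, liver and lung, 1 for interferon response in hindlimb, 1 and 2 for endothelium in heart and lung, and 1 for Y-linked genes in heart. Adjusted over the list alone, 1 endothelial gene was lower in heart and 1 hypoxia gene was higher in hindlimb. Medians of some uncalled lists still lay at the edge of random lists, such as hypoxia and glycolysis in liver (-0.16, percentile 0) and endothelium in lung (0.21, percentile 100). The proliferation list in lung, with a median of 0.0025, lay at percentile 97.59, and at 97.47 with FPKM of at least 1.

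Calls were shared between organs. Of 254 genes called in at least 1 organ, 28 were called in 2 or more in 1 direction, 9 higher and 19 lower. In every pair of organs and direction, fewer than 1 shared gene was expected from the numbers of calls, and heart and lung, for example, shared 7 lower genes against 0.115. Expected numbers assume independent organs, but 10 of the 17 embryos gave more than 1 organ, though heart and lung had no embryo or litter in common. Glo1, Gm9825 and Rps2-ps10 were higher, and Cdkn1a and Rnps1 lower, in all 4 organs. Dnah8, an axonemal dynein, was higher and Myl1, a myosin light chain, lower in 3. Of the 28 genes, 10 were on chromosome 17.

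The reporter assay asked which pieces of the locus change the amount of tag RNA. A tile from the intron of Trp53cor1 at 29076940 to 29077029 had the largest excess, with 3.78% ± 0.316 of RNA tags (SD, n = 3) against 0.107% ± 0.00111 of vector tags (SD, n = 3), 35.0-fold by limma (log2 5.13, SE 0.06, adjusted p = 1.74e-10). Of 431 tested tiles, limma called 42 with a larger and 258 with a smaller share of RNA than of vector tags, and 131 were not called. The median tile lay at -0.33 on the log2 scale, and the cause was not tested. With libraries centred on their medians, a shift of 0.26, the split was 59 higher and 61 lower, 49.2% higher against 14%. At 2-fold or more, 14 tiles were higher and 4 lower. Correlations of log2 tag shares between libraries of a kind were 0.929 to 0.942 for RNA and 0.994 to 0.995 for vector, across tags, which are not independent replicates.

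Tiles with an excess lay in several parts of the locus. The intron had 34 higher and 212 lower of 358 tested tiles, exon 2 had 4 and 39 of 57, exon 1 had 1 and 1 of 4, and the region upstream had 3 and 6 of 12. With centred libraries the counts were 47 and 53 in the intron, 7 and 8 in exon 2, 1 and 0 in exon 1, and 4 and 0 upstream. The tile at 29078998 to 29079087, which begins 37 bases upstream of the Trp53cor1 start, was 6.29-fold higher (log2 2.65, SE 0.09, limma adjusted p = 1.22e-07), with 5 tags at a mean log2 ratio of 2.75 and an SD of 0.39. Its sequence is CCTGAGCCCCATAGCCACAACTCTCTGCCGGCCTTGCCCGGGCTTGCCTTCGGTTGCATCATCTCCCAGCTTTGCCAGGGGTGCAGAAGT. The overlapping tile at 29078949, across the start of exon 1, had a log2 ratio of 1.88 (SE 0.13).

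The top intronic tile has the sequence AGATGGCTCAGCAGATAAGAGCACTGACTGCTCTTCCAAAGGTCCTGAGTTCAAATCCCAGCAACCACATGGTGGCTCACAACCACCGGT, and its 4 usable tags had an SD of 0.18 on the log2 scale. Intronic tiles starting at 29064383 (log2 2.94, SE 0.05), 29075862 (2.87, SE 0.07), 29064138 (2.71, SE 0.08), 29064432 (2.64, SE 0.20), 29074969 (1.52, SE 0.09), 29067176 (1.39, SE 0.05) and 29064089 (1.21, SE 0.06) completed the 10 largest. Tags did not carry all of them equally. The tile at 29064383 had a tag SD of 1.82 and a rank test adjusted p of 0.0570 by the exact Mann-Whitney test of its tags, the tile at 29067176 had 1.51 and 0.860, and the tile at 29064432 rested on 1 tag. Over 297 tiles with at least 3 usable tags, the median SD between tags was 0.26 (quartiles 0.18 and 0.36), and 72.8% of the variance of tag ratios lay between tiles.

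**Figure D4:**
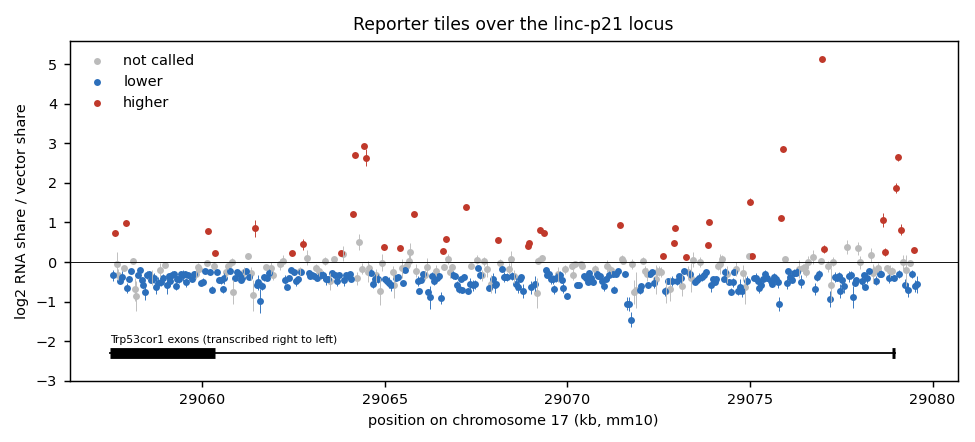
Log2 ratio of RNA to vector share (vertical, bars are the standard error from limma, 3 RNA and 3 vector libraries) of each tested tile along chromosome 17 (horizontal, kb), with Trp53cor1 exons as black boxes below. Red tiles were called higher (42) and blue lower (258), the highest lay at 5.13 in the intron, and tiles listed at 0 in RNA are drawn with the pseudocount.

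**Figure D5:**
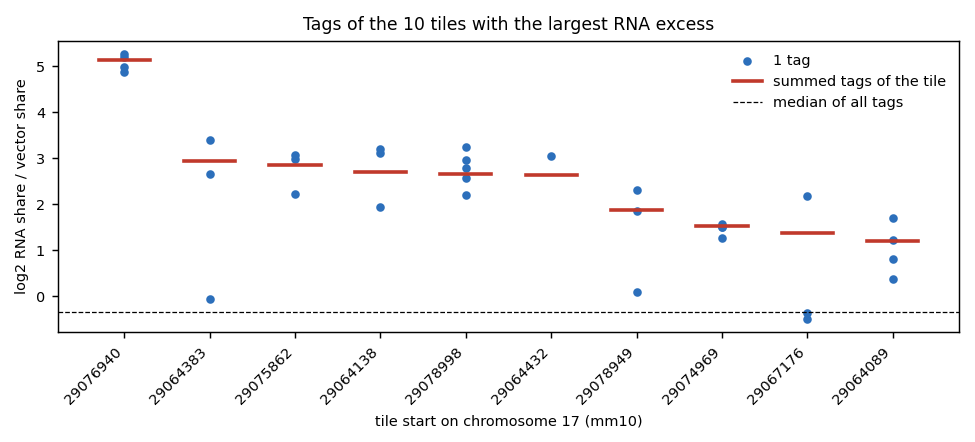
Log2 ratio of RNA to vector share of each usable tag (blue points) and of the summed tags (red lines) in the 10 tiles with the largest excess, by tile start on chromosome 17. The tags of the top tile lay close together (SD 0.18), and those of the tile at 29064383 spread widely (SD 1.82).

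Neighbouring tiles overlap, and calls came in runs. Of the higher tiles, 20 lay in 10 runs of 2, such as 29064383 to 29064521 with a mean log2 ratio of 2.79 and 29078949 to 29079087 with 2.27. Of the lower tiles, 229 lay in 59 runs, the longest of 13 tiles from 29058981 to 29059658 in exon 2, of which 1 was lower with centred libraries. The 5 tiles with the largest deficit were intronic. Those at 29071686 and 29071637 were listed at 0 in RNA, and those at 29075764 (log2 -1.07, SE 0.17), 29071588 (-1.06, SE 0.17) and 29061541 (-0.99, SE 0.30) were the others. The latter had, in that order, 2, 0 and 1 usable tags and RNA shares of 0.00685%, 0.00114% and 0.00280%. The lowest listed tag share was 8.54e-06 to 9.69e-06 in RNA and 5.59e-06 to 7.81e-06 in vector libraries. A tag near that level can thus be listed in vector and at 0 in RNA, and how far this made the deficits was not tested.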

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

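All alternatives with FPKM of at least 1, without chromosome 17, with a pseudocount of 1 on Cdkn1a, within 2 Mb, with centred libraries, with a pseudocount of 1e-06, on selected tags and by a rank test of tags were chosen after the data were seen. Of 88 alternatives 69 stayed within the range set for their result and 19 moved outside it. Counts of calls cannot change sign, so no reversal could arise for them. Trp53cor1 on the log2(FPKM + 1) scale was -0.89, -0.77, -0.05 and -0.13 in heart, hindlimb, liver and lung, and -3.25, -3.02, -0.43 and -0.95 with a pseudocount of 0.1, since it is expressed near the pseudocount. With a pseudocount of 1, Cdkn1a was at -1.46, -2.04, -1.04 and -0.79. Without chromosome 17, 21 genes were called in heart and 33 in liver, and 18 genes were shared between organs. Chromosome 17 held 10 and 21 of the calls lost, and 4 more in each organ were lost on adjusting again without it. Within 2 Mb, 3, 3, 4 and 4 genes were called, because more were counted. With FPKM of at least 1, 6 gene lists in liver lay outside the central 95% of random lists against 10. Limb patterning, epidermis, and neurons and Schwann cells were no longer scored, with fewer than 5 members left. Skeletal muscle moved inside, from percentile 0 to 3.625. In the reporter assay centred libraries gave 61 lower tiles, since centring moves all tiles up. A rank test of tags gave 24 higher and 5 lower of 297 tiles. It set the log2 ratios of a tile's tags against those of all other tags, and the median over all tags was -0.33. Higher and lower there are thus relative to other tags, not to equal RNA and vector shares. The test and the tiles changed too, since 37 of the 42 higher tiles had the 3 tags it needs.

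The replicate numbers did not pair the reporter libraries: same-numbered deviations correlated at -0.01, -0.06 and 0.03, and the replicate block gave 40 higher and 259 lower tiles. Without 1 library in turn, 36 to 48 tiles were higher and 196 to 281 lower, with the top tile at 5.08 to 5.20. No paired analysis was possible for the organs because the tables hold 1 value per genotype. The planned count tests, library normalizations, count filters, litter block, sex covariate, single libraries and estimated inter-gene correlation were not run there, nor were the count tests and vector count minimums of the reporter assay.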

Other observations

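The tests of chromosome 17, lung, hindlimb and the B box were chosen after the results were seen; those of library splits, GC content and 12 activator motifs were chosen before.

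A few genes went opposite ways in different organs. Spp1, osteopontin, was higher in KO heart and liver and lower in KO hindlimb, and the embryonic globin Hbb-bh1 was lower in heart and higher in hindlimb. Krt5 and Myh6 were higher in KO liver and lower in KO lung. These differences between organs were not tested. Rps2-ps10, a retrocopy of the chromosome 17 gene Rps2, was higher in all 4 KO organs while Rps2 itself was not called in any. No test of reads shared between them is reported here. Of 14 untested reporter tiles, 1 had RNA tags in at least 1 library and 0 in all 3.

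Calls clustered on chromosome 17. Action of the locus on genes within 1 Mb cannot be the whole account, since the odds ratio over distinct genes was 4.39 (95% interval 3.07 to 6.15) with those genes left out. Between 1 and 25 Mb from the locus 6.70% of 642 genes were called against 0.48% of 208 beyond, and 1.23% on other chromosomes. Strain sequence kept around the targeted allele could leave such a block. The test set for it asked for a share that falls with distance. The share was 5.41% from 1 to 5 Mb, 7.38% from 5 to 25 Mb and 0.48% beyond. A kept block need not thin steadily within its bounds, so the rise inside 25 Mb does not count against strain sequence. Action of the locus over many Mb was not separated from strain sequence. Cdkn1a, within 1 Mb of the locus, would lie inside such a block as well, so the source stays open.

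Heart muscle genes were lower in KO lung. Whole heart carried into the WT lungs would bring ventricular and atrial genes alike, yet the difference between WT and KO lung was 0.0239% of WT heart FPKM at the median of 3 ventricular genes and 13.6% at that of 4 atrial genes. Atrial or pulmonary vein muscle in the WT lungs could give 13.6%, but the genes were unequal, with Sln at 89.1%, Myl7 at 19.1%, Nppa at 8.05% and Myl4 at 6.13%. How much such muscle was dissected with each lung and a change of it in the mutant stay open, untested.

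Called muscle and skin genes were lower and called globins higher in KO hindlimb. Younger KO embryos are a candidate explanation, since embryonic globins rose by 0.758 more than adult ones on the log2 scale (medians 1.02 and 0.27), and litters differed between genotypes. The adult globins were split, with Hba-a1 (0.72) and Hba-a2 (0.64) called higher and Hbb-bs (-0.17) and Hbb-bt (-0.10) not called. More blood would dilute all other genes alike. The median of 34 skeletal muscle and epidermal genes lay at -0.45 against other genes (quartiles -0.62 and -0.29), whose own median was 0.01. These lists were chosen because their genes had been seen to fall, so their low median restates that fall. It shows only that dilution of all genes alike does not describe these genes, and it leaves blood open for the globins. In heart the embryonic globins went the other way (Hbb-bh1 at -0.83, called, and Hbb-y at -0.86 and Hba-x at -0.88, not called), although 1 KO embryo gave both organs, so the age difference stays open.

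In the reporter assay, the 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 300 tiles, was the only 1 to call as many, and the highest other called 0. GC content followed the log2 ratio at a Spearman rho of 0.302 across tiles, just over the bound of 0.3 set in advance. Of 12 activator motifs 0 were enriched among higher tiles (smallest adjusted p 0.646). Several top tiles looked like SINE repeats by eye, without a repeat annotation, and the B box, an internal promoter element of RNA polymerase III, was in the listed strand of 12 tested tiles, 9 of which were higher (75%) against 33 of 419 others (7.88%), and in the opposite strand of 12, of which 2 were higher (16.7% against 9.55%). The sources used here do not say which strand was cloned. That count includes 6 of the 10 largest tiles, which prompted the idea. Without those 10 and every tile overlapping them, 2 of 4 with the box were higher against 27 of 403 (Fisher's exact test, p = 0.0269, adjusted p = 0.108 over the 4 combinations of box and strand tried), so transcription from such repeats may or may not add to the tag RNA, and the source stays open.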
